A study of Mus musculus with 8 samples.

How the data were processed

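Dorsal root ganglia are the clusters of sensory neuron cell bodies, with their glia, beside the spinal cord. RNA from ganglia of Swiss Webster mice, an outbred stock, that had received saline was measured in 8 libraries, of which 4 are labelled male and 4 female, each numbered 1 to 4. Per the labels' protocols, total RNA was extracted with TRIzol, depleted of ribosomal RNA with RiboCop, and made into 3′ end libraries with Lexogen's QuantSeq kit, in which a transcript gives reads near its 3′ end whatever its length. The labels do not say whether a library came from one animal or from several, so the p-values measure the spread between these samples, which may be partly technical.

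The authors deposited 1 table per sex with 1 column per library, both listing the same 48431 genes. The submitters' processing notes name FastQC 0.11.5, TopHat2 2.1.1, Bowtie2 2.2.9 and Cufflinks 2.2.1 and the mouse builds mm10 and GRCm38.p4, without saying what each tool did; the gene annotation, strand setting and filters are not given in the sources used here. The values the authors deposited are named TPM, but the numbers behave as CPM, that is, reads per 1000000 counted reads. Each library summed to 1000000, and among the values above 0 and below 200 reads, between 98.3% and 98.6% per library were whole multiples, within 0.05 of a read, of 1 step that was the same for every gene, where chance would give 10%. A division by gene length would have given each gene its own step. The values are therefore called CPM here; the test chosen for TPM before the data were examined, on log2 values with a pseudocount, is the same for CPM. The step also gives the depth, between 7497800 and 12155800 counted reads per library. Since a few fractional values remained, no count model was used. Floors of 3 reads and 95% exact binomial intervals cover counting error only.

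Rows that share a gene symbol were summed, which concerned 110 symbols and left 48315. Genes with a mean of at least 1 CPM over the 8 libraries were tested, 14505 in all, as log2(CPM + 1). Fold changes are on that scale, which understates the change of low genes, and are female minus male by label. The main test was limma's moderated test with a trend of variance on level (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. It was checked on simulated values with the real means and spreads, drawn independently for each gene. With 8 libraries it recovered 21% of 100 genes changed 2-fold and 77% of 100 genes changed 4-fold, with 5 false calls. With 6 libraries the shares were 1% and 39%, with 1 false call. Real genes vary together, so these shares and false calls may not carry over to the real libraries.

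Fixed before the data were examined were 42 gene lists of neuron classes, channels, glia, other cell types and cell functions. Of these, 2 served to check sex and 39 had at least 5 tested genes. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 39 lists. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, one way. A list score is the mean log2(CPM + 1) of its tested members in a library; scores were compared by an exact two-sided permutation test over 70 assignments of the 8 libraries, whose smallest p is 0.0286, adjusted over the 42 lists. With 6 libraries the smallest p of that test is 0.1.

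The rule for named genes was also set before the data were examined. It took up to 12 genes per direction that passed the threshold with no overlap between the sexes, filled up to 5 with the smallest unadjusted p. It added the members of each list with the smallest p, of which the first 2 were kept, as well as Xist, the Y-linked genes, Prlr, Esr1, Esr2, Calca, Trpv1 and Scn10a, and the 5 most abundant genes of each sex. Some genes that the rule takes are not reported here. Where a gene outside the rule is named, it was chosen after its values were seen. Positions are from the GENCODE M21 annotation of GRCm38, 1-based, matched by gene identifier, which found 48052 of 48431 (99.2%).

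Alternatives set beforehand were 2 other pseudocounts, 2 other filters, 3 other scalings, other variance models, array weights, the replicate number as a block and leaving out each library in turn. Chosen after seeing the data were leaving out both replicate 1 libraries, with or without male 2, a term for the side of the first principal component or a fit within each side, leaving out 3 genes of a ribosomal RNA locus, and mean-variance weights. All 28 pairs of libraries differed in their values, and no sample was counted as a duplicate. Figures were drawn with matplotlib 3.10.9. Ribosome profiling named in the study's design was not analysed here.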

Results

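The design set male against female dorsal root ganglia of saline-treated mice, with 4 libraries labelled male and 4 labelled female. The libraries labelled male 1 to 4 held 8184270, 9194300, 10198900 and 9750260 counted reads, and those labelled female 1 to 4 held 11094000, 12155800, 7934720 and 7497800, a 1.62-fold range. In these libraries 3 reads correspond to between 0.247 and 0.40 CPM. All groups below are those of the labels.

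The sex-specific transcripts did not match the labels of both replicate 1 libraries. Xist, the RNA that silences one X chromosome in female cells (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), stood at 294 CPM in the library labelled male 1 (2408 reads, 95% exact binomial interval 283 to 306) and at 0.270 CPM in the library labelled female 1 (3 reads, interval 0.0558 to 0.790). Ddx3y, a Y-linked RNA helicase (ENSMUSG00000069045.11, chromosome Y, 1260771 to 1286629), stood at 0.855 CPM in male 1 (7 reads) and at 102 CPM in female 1 (1134 reads). In the other 6 libraries Xist was 277 ± 101 CPM in those labelled female (SD, n = 3) and 3.17 ± 2.0 CPM in those labelled male (SD, n = 3), and Ddx3y was 0.369 ± 0.0364 and 90.3 ± 35.1 CPM. The Y-linked genes Eif2s3y, Uty and Kdm5d and the Y-linked non-coding RNA Gm29650 followed Ddx3y, with 15.1, 15.5, 9.01 and 10.3 CPM in female 1 and 0.367, 0, 0.367 and 0 CPM in male 1. Over all 8 libraries the difference of Xist by label was 2.60 on the log2 scale, with an exact permutation p of 0.429. Whether reads were counted by strand is not known, so Xist cannot be told from its antisense partner Tsix, and the few reads of Y genes in libraries without them could not be told from their X-linked copies.

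**Figure D1:**
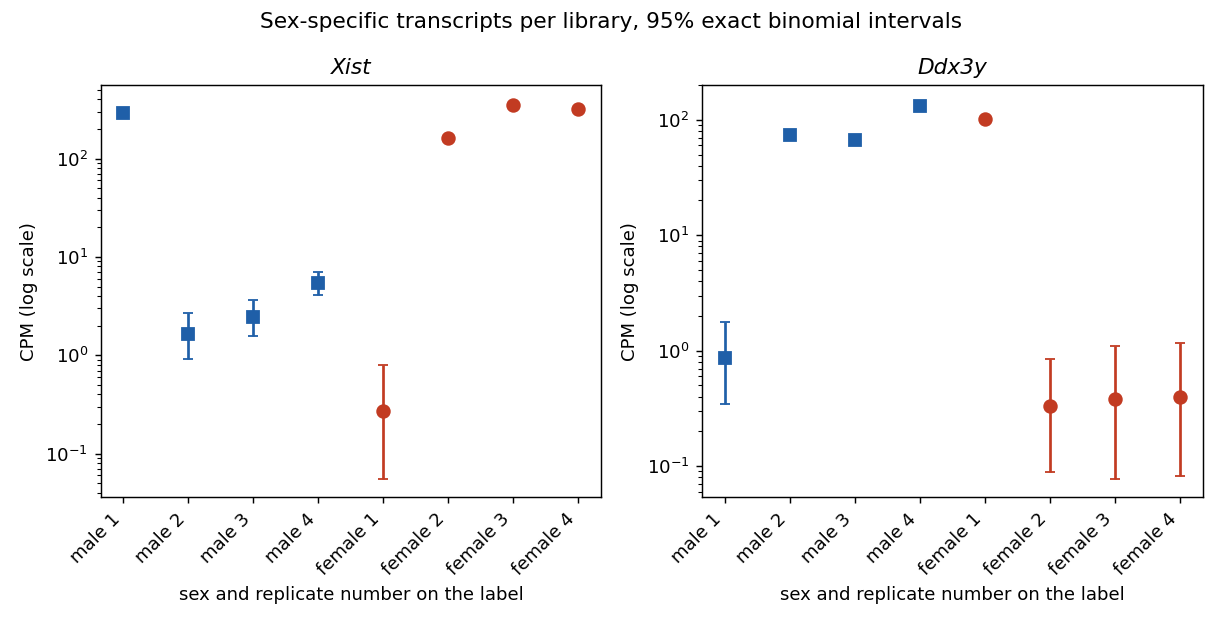
CPM of Xist (left) and Ddx3y (right) on a log axis for each library, named by the sex and replicate number on its label; squares are labelled male, circles labelled female, and bars are 95% exact binomial intervals. The library labelled male 1 has 294 CPM of Xist and 0.855 CPM of Ddx3y, and the library labelled female 1 has 0.270 and 102 CPM.

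The question of the main comparison is which genes differ between ganglia of the sexes. By the labels as given, no gene passed the threshold between female and male ganglia. Limma called 0 of 14505 genes, with a smallest adjusted p of 0.446, while 1595 genes (11%) had an unadjusted p under 0.05. A count of 0 does not show equal expression, since the replicate 1 libraries were counted by labels that their sex genes did not match. Mean-variance weights also called 0, with 1628 genes at an unadjusted p under 0.05. Of those 1595 genes, 397 had higher values in the libraries labelled female and 1198 in those labelled male. The median log2 difference of all genes was −0.18, and −0.02 after median ratio scaling, so single differences are to be read against that shift. The groups did not overlap for 613 genes (4.23%, where chance gives 2.86%). The count of 0 depended on female 2 and on equal weights of the libraries, and stayed 0 without each of the other 7. Without female 2, 1354 genes passed, 242 higher and 1112 lower in the libraries labelled female, and with array weights 4363 passed, 1170 higher and 3193 lower.

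The genes with the smallest p among those with lower values in the libraries labelled female included the non-coding RNA Miat, the osmotic stress transcription factor Nfat5, Gramd4, the zinc finger gene Zfp266 and the glycolytic enzyme Adpgk. Miat (ENSMUSG00000097767.8, chromosome 5, 112213228 to 112229395) had 81.2 ± 33.6 CPM in libraries labelled male (SD, n = 4) and 28.7 ± 6.0 CPM in those labelled female (SD, n = 4), a log2 difference of −1.40 with an SE of 0.30 and a limma adjusted p of 0.446. The corresponding log2 differences were −1.19 for Nfat5, −1.15 for Gramd4, −1.12 for Zfp266 and −1.09 for Adpgk. In the other direction were C1qa, a subunit of the complement protein C1q made by macrophages (106 ± 28.2 CPM by male label, 218 ± 53.9 CPM by female label, log2 difference 1.04, SE 0.26), the translation initiation factor gene Eif3c (380 ± 71.2 and 732 ± 184 CPM), Medag (12 ± 0.706 and 23 ± 6.1 CPM), the methionine sulfoxide reductase gene Msrb2 (47.5 ± 5.73 and 75.5 ± 8.73 CPM) and the low-level gene Serpina11 (0.319 ± 0.234 and 2.09 ± 1.21 CPM; SD, n = 4 throughout). All 10 had a limma adjusted p of 0.446 over all genes. The 4 values behind each mean include the replicate 1 library whose sex genes did not match its label. Serpina11 stood at 0.122, 0.653, 0.294 and 0.205 CPM in male 1 to 4. In these libraries 3 reads correspond to 0.367, 0.326, 0.294 and 0.308 CPM, so its values by male label lie near the floor. Without female 2, Miat, Nfat5, Gramd4, Zfp266, Adpgk, C1qa, Eif3c, Medag and Msrb2 passed, with adjusted p from 0.0364 up to 0.0454, and array weights also called these and Serpina11. Female 2 was the only library labelled female on the negative side of the first principal component. Without it the label nearly followed that component, with 3 of 4 libraries labelled male negative and 3 of 3 labelled female positive. Array weights were lowest for female 2 (0.312) and for male 4 (0.437), the only library labelled male on the positive side.

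Genes that define sensory neurons did not pass the test. Calca, which encodes the neuropeptide CGRP of peptidergic nociceptors, had 521 ± 135 CPM in the libraries labelled male and 303 ± 228 CPM in those labelled female (log2 difference −1.03, SE 0.46, limma adjusted p = 0.446), and its log2 difference was −0.51 without the replicate 1 libraries. Without female 1 the log2 difference was −0.63, and without female 2 Calca passed, at −1.48 and an adjusted p of 0.0364. The heat and capsaicin receptor gene Trpv1 had 25.2 ± 9.47 and 19.2 ± 9.02 CPM, and the nociceptor sodium channel gene Scn10a had 703 ± 155 and 741 ± 128 CPM, with limma adjusted p of 0.586 and 0.860. Without the replicate 1 libraries both differences changed sign, from −0.41 to 0.05 for Trpv1 and from 0.09 to −0.03 for Scn10a, and that of Scn10a was also negative without male 2 (−0.06) or female 1 (−0.02). The pan-neuronal score was 8.4 ± 0.18 by male label and 8.43 ± 0.08 by female label (exact permutation p = 0.857). Among hormone receptor genes, the prolactin receptor gene Prlr had 2.31 ± 0.556 and 1.96 ± 0.837 CPM, from 14 to 25 reads per library, and the oestrogen receptor gene Esr1 had 5.78 ± 1.94 and 4.26 ± 2.04 CPM (limma adjusted p of 0.732 and 0.562). The sign of the Prlr difference turned under quantile normalization. Esr2 stayed under the filter, with between 0 and 9 reads per library.

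Among the gene lists, mitochondrially encoded genes and nuclear long non-coding RNAs had lower values in the libraries labelled female, with both replicate 1 libraries counted by their labels. Of the 12 mitochondrial genes tested, which encode subunits of the respiratory chain, 11 had a negative and 1 a positive log2 difference, with a median of −1.23 (camera adjusted p = 0.0217; adjusted p = 0.983 with an estimated correlation; fry adjusted p = 0.323). The complex I subunit gene mt-Nd1 had 1343 ± 735 CPM by male label and 511 ± 335 CPM by female label, and mt-Atp6 had 53.5 ± 32.1 and 20.2 ± 9.82 CPM; neither passed limma (adjusted p = 0.446), though mt-Nd1 did without female 2 (−1.85, adjusted p = 0.0364). The list's score was 7.77 in male 1 and 5.10 in female 1, the libraries whose sex genes did not match their labels. In the other 6 it was between 6.20 and 7.01. With the labels of male 1 and female 1 exchanged, the highest score would be a female one and the lowest a male one. Without those 2 libraries the log2 difference went from −1.46 to −0.75 for mt-Nd1 and from −1.32 to −0.70 for mt-Atp6. Of the 11 long non-coding RNAs, 10 had negative differences, with a median of −0.81 (camera adjusted p = 0.0217; adjusted p = 0.983 with an estimated correlation; fry adjusted p = 0.258). Neat1, the scaffold of nuclear paraspeckles, had 1293 ± 324 and 652 ± 206 CPM, and 0 members passed over all genes, while adjusted over the list alone 3 did, Neat1, Mir124a-1hg and Kcnq1ot1. The mitochondrial call was lost without male 1 (adjusted p = 0.0737), female 1 (0.0604) or female 2 (0.211), and that of the non-coding RNAs without male 4 (0.0848), female 1 (0.0604) or female 2 (0.211). Both kept the sign of their median under each scaling. The score of the non-coding RNAs was 7.63 in male 1 and lowest in female 1, at 6.14, and between 6.76 and 7.80 in the other 6.

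The other 37 lists did not pass camera, with adjusted p between 0.187 and 0.940, and in each of them 0 members passed over all genes. Voltage-gated calcium channels came closest in their scores, at 4.79 ± 0.15 by male label and 4.41 ± 0.12 by female label, with 12 of 14 members negative (exact permutation p = 0.0286, the smallest the design allows; 0.36 after adjustment). The calcium channel score was 4.79 in male 1 and 4.51 in female 1. Among the other 6 libraries it was 4.58 to 4.94 by male label and 4.27 to 4.51 by female label. With the labels of male 1 and female 1 exchanged, the groups would overlap. Under median ratio scaling 0 list scores had an exact permutation p under 0.05, and the median of the calcium channels went from −0.36 to −0.18. Their members Cacna1b, the N-type channel of presynaptic terminals, and the subunit gene Cacnb4 had 82.1 ± 15.4 and 348 ± 82.5 CPM by male label against 50.2 ± 14.9 and 207 ± 56.4 CPM by female label. The mitochondrial score had the same p, at 6.98 ± 0.58 and 6.02 ± 0.63. Of 16 myelinating Schwann cell markers, which belong to the glia that wrap axons, 15 were negative, with a median of −0.61 (camera adjusted p = 0.187), and Pmp22, a myelin protein gene, had 2278 ± 774 and 1280 ± 874 CPM. Peptidergic nociceptor markers had a median of −0.47 with 11 of 13 negative (0.660), and satellite glia markers −0.32 with 9 of 14 negative (0.843), where 67.5% of all tested genes were negative. Under median ratio scaling the medians were −0.42, −0.28 and −0.13 for the Schwann cell, nociceptor and satellite glia markers. Macrophage markers had a median of 0.09, with 8 of 15 members positive (0.187), and only C1qa passed when adjusted over the list alone, as it also did in the antigen presentation and complement list.

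**Figure D2:**
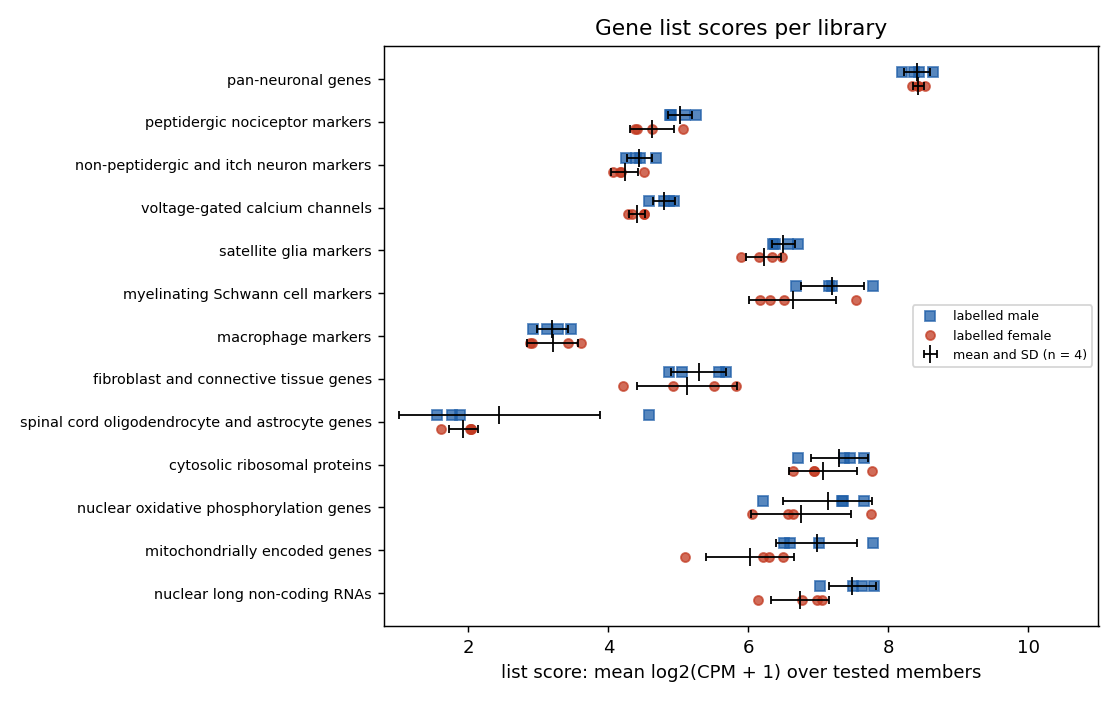
Score of 13 gene lists in each library, as the mean log2(CPM + 1) over tested members; squares are labelled male, circles labelled female, and black bars give the mean and SD of 4 libraries. Mitochondrially encoded genes lie at 6.98 ± 0.58 by male label and 6.02 ± 0.63 by female label, the pan-neuronal genes at 8.4 ± 0.18 and 8.43 ± 0.08, and male 2 stands at 4.58 in the spinal cord list.

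With both replicate 1 libraries left out, a comparison chosen after the sex check, 6 genes passed by label and all lie on the sex chromosomes. They are the genes whose values led to that choice, so their p-values restate it and are no independent test of sex. Xist was higher in the libraries labelled female, by 6.09 on the log2 scale with an SE of 0.41 (limma adjusted p = 0.00169). On the Y chromosome Ddx3y had a log2 difference of −5.99 (adjusted p = 0.000608), Eif2s3y, a translation initiation factor gene at 1010543 to 1028847, −4.47 (0.00124), Uty, a histone demethylase gene at 1096861 to 1245759, −4.15 (0.00575), Kdm5d, another histone demethylase gene at 897788 to 956786, −3.12 (0.0267), and Gm29650, at 1048393 to 1049134, −2.77 (0.0267). The other genes of the Y list, Zfy1, Zfy2, Usp9y, Uba1y and Sry, stayed under the filter. Outside the sex chromosomes 0 genes passed, and 352 of all tested genes (2.43%) had an unadjusted p under 0.05. The groups did not overlap for 1101 genes (7.59%, where chance gives 10%). Serpina11 had a log2 difference of 1.35, Medag 0.93, Loxl1 0.78 and Kng2 0.99, with a limma adjusted p of 0.946 each. With male 2 also left out, 4 genes passed, Xist, Ddx3y, Eif2s3y and Uty.

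In these 6 libraries camera called 5 lists, with all-gene median −0.12 beside them. Fibroblast and connective tissue genes (median 0.16, 14 of 18 positive, adjusted p = 0.00326), macrophage markers (median 0.08, 10 of 15 positive, 0.0168) and cytosolic ribosomal proteins (median −0.09, 34 of 77 positive, 0.0168) ranked toward the libraries labelled female. Voltage-gated calcium channels (median −0.45, 12 of 14 negative, 0.0168) and neutrophil and bone marrow markers (median −0.46, 10 of 10 negative, 0.0460) ranked toward those labelled male. The median of the ribosomal proteins and their camera direction differ in sign, and the median turned positive under median ratio scaling. Over all 8 libraries the fibroblast list had a median of −0.22, with 4 of 18 members positive. With an estimated correlation all 5 had an adjusted p of 0.992, and fry called 0 lists. The mitochondrial genes (median −0.44, camera adjusted p = 0.137) and the long non-coding RNAs (−0.51, 0.0601) did not pass there.

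The most abundant transcripts included ribosomal, nuclear non-coding and chaperone RNAs. The mitochondrial ribosomal RNA gene mt-Rnr2 had 44308 ± 10146 CPM by male label and 56586 ± 27201 CPM by female label, the nuclear non-coding RNA Malat1 18169 ± 14271 and 10256 ± 5406 CPM, and the chaperone gene Hsp90ab1 9140 ± 2907 and 14258 ± 4105 CPM; none passed limma (adjusted p of 0.832, 0.574 and 0.473). The log2 difference of mt-Rnr2 was 0.23 as deposited and 0.43 under median ratio scaling. It was 0 under quantile normalization, which gives values of equal rank the same value, so that 0 does not show equal levels. Genes at one ribosomal RNA locus on chromosome 17, the overlapping AY036118 (39847113 to 39848035), Rn18s-rs5 (39846353 to 39848827) and Gm42418 (39846958 to 39848788), were listed at exactly 0 in male 4, female 3 and female 4. In the other 5 libraries AY036118 stood at 46216, 25395, 34747, 43401 and 20085 CPM (male 1, 2 and 3, female 1 and 2). They were the only 3 genes at 0 in those libraries and above 1 CPM in the rest, and reads shared between them could not be assigned to one.

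The libraries differed more along a direction that ran across the labels than by label. The first principal component held 59.3% of the variance and the second 13.4%. The libraries labelled male 1, male 2, male 3 and female 2 had scores of −44.2, −59.2, −23.6 and −52.3 on it, and male 4, female 1, female 3 and female 4 had 30.3, 58.3, 49.9 and 40.8. By label the scores differed by 48.3 (exact permutation p = 0.2). Pairs of libraries on the same side correlated at 0.955 to 0.982 across genes and pairs on opposite sides at 0.900 to 0.954, where genes are not independent replicates. With the side as a term, limma called 0 genes by label, and 1417 had an unadjusted p under 0.05. Within each side the labels had 3 libraries against 1, so that a difference there describes the lone library.

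**Figure D3:**
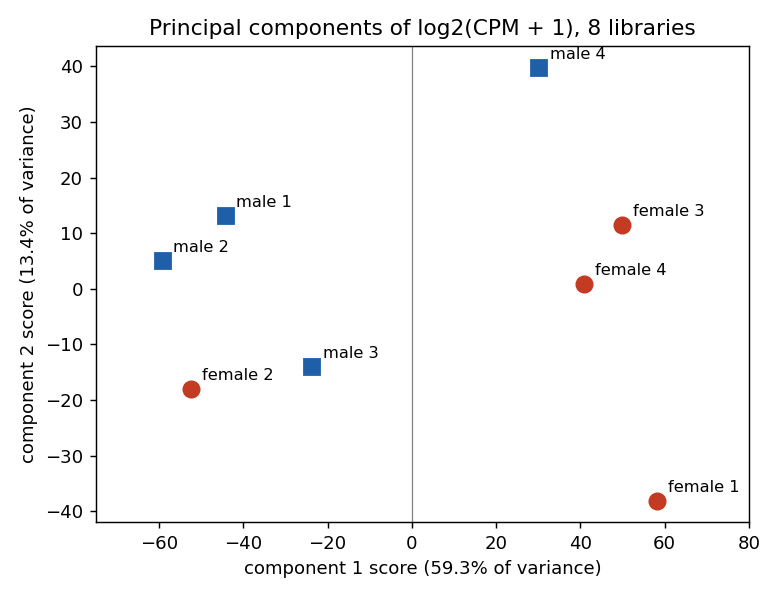
Scores of the 8 libraries on the first (59.3% of variance) and second (13.4%) principal components of log2(CPM + 1); squares are labelled male, circles labelled female. The libraries labelled male 1, 2 and 3 and female 2 lie below 0 on the first component and the other 4 above it.

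The library labelled male 2 held transcripts of central nervous system cells that were low in the other 7. Mog and Mobp, made by oligodendrocytes, the myelinating cells of the brain and spinal cord, stood at 37.1 and 56.0 CPM there and at most at 1.23 and 5.03 CPM elsewhere. The astrocyte transporter genes Slc1a2 and Slc6a11 stood at 58.8 and 57.8 CPM against at most 8.19 and 5.51, and the inhibitory neuron transporter genes Slc32a1 and Slc6a5 at 64.7 and 14.9 CPM against at most 1.73 and 1.64. Chat, a marker of motor neurons, was at 0 in male 2. The list score was 4.58 in male 2 and between 1.55 and 2.03 in the other libraries. Compared by label, it had an exact permutation p of 0.914.

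**Figure D4:**
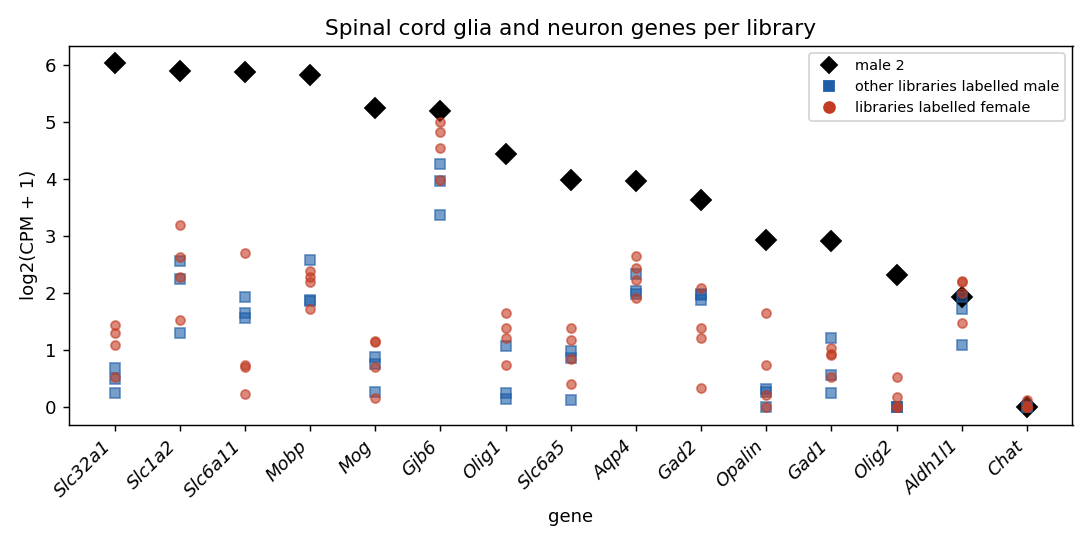
Log2(CPM + 1) of the 15 genes of the spinal cord list that no Schwann cell list holds, with male 2 as black diamonds, the other libraries labelled male as squares and those labelled female as circles. Male 2 is highest for 13 genes, the exceptions being Aldh1l1 and Chat.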

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

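The tests on the sex genes and on the spinal cord genes and the counts of splits were chosen only after the result was seen. In 29 of 290 groups (41 list scores and 104 genes, each by label), 1 of the 4 libraries of a label stood apart from the other 3. The ratio of its gap to the whole range exceeded Dixon's 95% critical value, where chance gives about 1 in 20. The 29 include the sex genes of the replicate 1 libraries, given next, so that share cannot tell whether the other values were in excess.

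The replicate 1 libraries stood apart in their sex genes. In female 1 the ratios were 0.988 for Ddx3y, 0.957 for Eif2s3y, 0.907 for Gm29650, 0.879 for Uty, 0.861 for Kdm5d, 0.864 for Xist and 0.946 for the Y-linked score. In male 1 they were 0.890 for Eif2s3y, 0.845 for Ddx3y, 0.841 for Gm29650 and 0.836 for the Y-linked score.

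RNA of both sexes mixed in each library is argued against: the 5 Y genes summed to 13 reads in male 1, 1.05% of the mean of the other libraries labelled male with an upper 95% limit of 1.79%, and Xist in female 1 reached 0.0976% of the mean of the other libraries labelled female. In 12 of 12 comparisons of a sex gene in one of these libraries, the value lay nearer to the remaining libraries of the other label, which restates the pattern and decides nothing about its origin. An exchange of animals, tubes or column names and 2 independent wrong labels stay open. The split of the 8 libraries that exchanges both labels called 6 genes, of which 0 lie beyond the 6 sex chromosome genes, which again restates the pattern. It also called 11 lists, where splits other than the labels as given had a median of 6.5 lists and a highest of 12.

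In male 2 the ratios were 0.938 for Gad2 and 0.914 for Slc6a11, both in the spinal cord list, 0.892 for the score of that list, and 0.830 for Penk, an opioid peptide gene. In female 1 the same score was lowest among the libraries labelled female, at 1.61 against 2.02 to 2.03 (ratio 0.956).

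More myelinating Schwann cells in male 2 are argued against, since female 2, with the next highest Schwann cell score, had a spinal cord score lower than that of male 2, by a difference of 2.55. Of the 15 list genes that no Schwann cell list holds, 13 were highest in male 2 among the 8 libraries, with Slc32a1 at 64.7 and Mobp at 56 CPM and Chat at 0, which restates the pattern; 2 of the list's 17 genes are also in Schwann cell lists. Spinal cord tissue taken with the ganglia and a mix with RNA of another sample stay open. No biological explanation was tested, since the design names none.

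Other libraries stood apart from those of the same label in single values. Among libraries labelled male, in male 4 AY036118 (0.944) and Rn18s-rs5 (0.942) of the ribosomal RNA locus were at 0, Msrb2 (0.919) was highest, and the adipocyte score (0.873) and heat shock score (0.865) were lowest, at 3.32 and 6.85. Among libraries labelled female, in female 2 the immune genes Ighm (0.934), S100a9 (0.929), H2-Eb1 (0.846) and S100a8 (0.842) and the low-threshold C fibre score (0.905) were highest and the clock gene Cry1 (0.908) was lowest. Rtp4, an interferon-induced gene, was highest in male 1 (0.861), and Tagln, a smooth muscle gene, in male 3 (0.847), both among libraries labelled male; Tagln was higher in all 4 libraries labelled female.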

How the results depend on the processing

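The alternatives that leave out both replicate 1 libraries, with or without male 2, those with the side of the first component, that without the ribosomal RNA locus and mean-variance weights were chosen only after the result was seen. Of 2791 values of 104 named genes under the alternatives, 2660 kept their side of the threshold and 131 passed it; 54 values that did not pass changed sign. Of 818 values of 39 lists, 747 kept their side, 45 passed, 14 no longer passed and 12 passed in the opposite direction. Array weights, between 0.312 for female 2 and 3.13 for female 4, called 4363 genes. Female 2 and male 4 (0.437) had the lowest weights and lay on the side of the first component with most libraries of the other label. The 4363 genes can therefore not be read as a difference by label alone. Leaving out each library in turn gave between 0 and 1354 genes, the latter without female 2 and 0 without each other one, and between 0 lists (without female 1) and 4 (without male 2 or female 3). The cause was not tested.

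Without both replicate 1 libraries, 6 genes and 5 lists passed, and 0 list scores had an unadjusted exact permutation p under 0.05, which 3 libraries against 3 cannot give. Without male 2 as well, 4 genes and 9 lists passed. With the side as a term, 10 lists passed, and with both replicate 1 libraries also left out 7 genes, Gm37899 beside the 6 sex chromosome genes, and 13 lists. Within the negative side 14 lists passed, and within the positive side 7 lists and 4 genes (Myh7, Gm20716, Gm26871 and 9530059O14Rik, like Gm37899 named after their values were seen). Those fits set 1 library, female 2 or male 4, against 3 and assume that it varies like them, so they describe that library and not the sexes. Under median ratio scaling 0 list scores had an unadjusted exact permutation p under 0.05, against 2 as reported, of which 0 passed after adjustment. With an estimated correlation 0 lists passed, and by fry 0.

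Among lists that did not pass as reported, some passed in the opposite direction, with these medians. The spinal cord list had 0.19 without male 2, where its medians over single omissions started at −0.91, and 0.39 without male 2 and both replicate 1 libraries. Nuclear oxidative phosphorylation genes had 0.22 without those 3 libraries, 0.28 with the side as a term, 0.36 with that term and without both replicate 1 libraries, 0.30 within the negative side and 0.20 within the positive side. With the side as a term and without both replicate 1 libraries, adipocyte genes had 0.27 and antigen presentation genes 0.27. Within the negative side, interferon response genes had 0.29 and antigen presentation genes 0.45. Muscle genes had −0.19 there and −0.10 as reported, so their camera direction turned and the sign of their median did not. The cause was not tested.

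Whether the replicate numbers pair the samples cannot be told from these values. The deviations of same-numbered libraries correlated at −0.31, 0.70, −0.15 and 0.44 across genes, which are not independent replicates. Those of differently numbered libraries ran from −0.81 (male 4 and female 2) to 0.47 (male 1 and female 2). With the replicate block 0 genes passed, 2694 had an unadjusted p under 0.05 and 2 lists passed, Schwann cell markers (adjusted p = 0.0402) in place of mitochondrially encoded genes (0.0504).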

Other observations

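The test of sex on the first component and the counts of splits were chosen only after the result was seen, unlike the tests on length and GC, abundant genes and depth. Several gene lists loaded toward one side of the first component. Set against 10000 random lists matched on mean level, the mean loading of cytosolic ribosomal proteins and of nuclear oxidative phosphorylation genes lay at percentile 0, with 61 of 77 and 66 of 74 members toward the side of male 1, male 2, male 3 and female 2. Myelinating Schwann cell markers (14 of 16 members), adipocyte genes (10 of 11), antigen presentation genes (16 of 19), fibroblast genes (16 of 18), interferon response genes (18 of 21) and heat shock genes (10 of 14) loaded toward the same side, all below percentile 1. So did spinal cord genes (15 of 15), whose score was 4.58 in male 2 and 1.55 to 2.03 in the other libraries of both sides, and mitochondrially encoded genes (9 of 12), whose scores overlapped between the sides apart from male 1 (7.77) and female 1 (5.10). Camera also called mitochondrially encoded genes by label over all 8 libraries, and ribosomal proteins and fibroblast genes without the replicate 1 libraries (adjusted p = 0.983 and 0.992 with an estimated correlation). Nerve injury genes lay at percentile 97.3 and pan-neuronal genes at 91.4, with members on both sides. These percentiles describe these libraries and are not a test between groups.

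Noradrenaline synthesis and transport genes, chosen after their values were seen, were unevenly present. Dbh stood at 11.7 CPM in male 1, 5.47 in female 4 and 1.48 in female 2, and at no more than 0.098 in the other 5 libraries. Slc6a2, the noradrenaline transporter gene, was highest in the same male 1 and female 4, at 8.31 and 5.33 CPM, as was Ddc, at 16.6 and 12.9 CPM. Th, which low-threshold C fibre neurons also express, did not follow them, with 45.9 CPM in male 1, 40.8 in female 2 and 8.27 in female 4.

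A few technical trends are argued against as the whole cause of the first component, which held 59.3% of the variance. It held 57.8% after each library's trends on gene length and GC content were removed, 57.5% without the 50 most abundant genes, the ribosomal RNA locus included, and 58.5% with every library thinned to 7497800 reads, each time with the same libraries on each side. Sex on the labels is argued against too, since 2 libraries, male 4 and female 2, lay on the side with most libraries of the other label. By their sex genes, male 1 and female 2 (high Xist) and male 2 and male 3 (Y genes) shared the negative side. On the positive side were female 3 and female 4 (high Xist) and male 4 and female 1 (Y genes). Differences in dissection, in RNA quality or in preparation day stay open and were not tested, since the labels record none. Mitochondrial ribosomal RNA held 2.93% to 4.89% of the reads on the negative side and 5.05% to 9.56% on the positive side. The libraries with the ribosomal RNA locus at 0, male 4, female 3 and female 4, lay on the positive side, where female 1 held 7.60% in it. Nuclear long non-coding RNAs loaded at percentile 16.4. These values were compared after the sides were known.

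The count of 0 genes by label leaves nothing to compare with chance, since any split gives at least 0 genes (35 of 35 here); the highest other split gave 5110. That split is the one that follows the sides of the first component. Those sides were taken from the same values, so its count restates that component and is no separate support for it. For the 2 called lists, 33 of the 35 splits gave as many and the highest other gave 12, so chance cannot be excluded for them. Without the replicate 1 libraries, 2 of the 10 splits gave 6 or more genes, the real one with 6 and another, which also follows the sides of the first component, with 4100, and 8 of 10 gave 5 or more lists, with a highest other of 12; 10 splits are too few for a share under 0.05.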
